A study of Mus musculus with 4 samples.

How the data were processed

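RNA of small intestine, from mice with and without the Cyp3a cluster, was labelled with Cy3 and read on 1-colour Agilent mouse arrays, per the labels. Samples were grouped by the genotype and replicate number in the labels, with 2 arrays each. Whether an array held RNA of 1 animal or of several is not given in the sources used here. Per the submitters' processing notes, images were read with Agilent Feature Extraction 11.5.1.1. The deposited intensity of each spot is, per the file headers, a background-subtracted and detrended signal not scaled between arrays. The files also hold median spot and background intensity and quality flags. The authors' processed value table holds log2 values whose scale the sources used here do not state. Set against the scanner files over 39408 probes, each of its columns had a correlation of 1.00 with log2 processed signal minus the array's 75th percentile and minus the probe's median over the 4 arrays, with all values within 0.01. Its column medians were 0.05, -0.10, -0.11 and 0.12 for wild type 1 and 2 and knockout 1 and 2. Since rows are centred, that table keeps differences between arrays but no levels.

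Control spots and spots with an outlier flag (91 to 129 per array) were left out, and spots of a probe were averaged as log2 processed signal. Each array was scaled by subtracting its 75th percentile. Of 39429 probes, 28025 matched 1 gene symbol through their accession in the RefSeq table of assembly GRCm38.p6, without versions, and 11404 matched none. The array's own annotation is of another build, so that table served only for names and for which genes neighbour each other, and no coordinates are given. Probes had to be well above background on at least 2 of the 4 arrays, which left 24006, of which 5266 had no symbol and entered only a test of each probe on its own. For each symbol the brightest probe was used, giving 14395 genes. Genotypes were compared with lmFit and eBayes with an intensity trend in limma 3.58.1 under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 55 gene lists were fixed before the data were examined, and the 52 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives.

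Genes are named by a rule also fixed beforehand. It takes all tested Cyp3a genes, the 12 largest folds per direction past the threshold without overlap, and up to 4 genes of smallest p per list. Since fewer than 12 passed, places were filled by the smallest unadjusted p among genes with at least a 2-fold difference and no overlap. Names outside this rule are said to be chosen after their values were seen.

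Wild type 2 and knockout 1 shared slide 2 and its scan, wild type 1 was alone on slide 1 and knockout 2 on slide 3. A fixed slide term leaves no residual degrees of freedom, and the slide correlation could not be estimated from 1 pair, so the difference within the shared slide is given instead. The alternatives were other background corrections and scalings, the authors' table, other filters and probe rules, other variance settings, a replicate block, and leaving out each array, where the lone array of a genotype is assumed to vary like the others.

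The fit was tested on simulated data with 14395 genes and 200 changed genes in 20 simulations. With variances drawn from the fitted prior it recovered 0.2% of genes changed 2-fold, 19.3% at 4-fold, 86.1% at 16-fold and 98.2% at 256-fold, and 5.65% of calls were false. With each gene's fitted variance the shares were 5.2%, 72.0%, 98.8% and 100%, and 11.1% of calls were false. A simulated shift of 0.4 (log2) in the cell cycle list was called in 17 and 20 of 20 simulations. Independent genes were simulated, so this says nothing about correlated ones.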

Results

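Gene expression was measured in small intestine of wild-type mice and of mice lacking the Cyp3a cluster, a block of neighbouring genes on chromosome 5 that encode cytochrome P450 enzymes oxidising many drugs and steroids. Each genotype had 2 arrays, and per the labels the 2 experiments used different animals. Each array carried 39429 different probes for mouse transcripts, of which between 55.1% and 64.4% were well above background on an array. The 75th percentile of signal was 226 and 356 in wild type 1 and 2 and 322 and 175 in knockout 1 and 2, and no spot was saturated. After naming and filtering, 14395 genes were tested. With 2 arrays per genotype, the number of arrays limits the precision of every value below. Levels are log2 signals relative to the 75th percentile of the same array, given as mean ± SD with n = 2, and differences are knockout minus wild type with the standard error (SE) of limma's fit.

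The first question was what the deletion did to the Cyp3a transcripts themselves. All 6 tested genes of the cluster fell to signals not well above background on the probe used, on both knockout arrays. Cyp3a11, which encodes a major drug-oxidising P450 of mouse liver and gut, had levels of 5.05 and 5.78 in wild type 1 and 2 and of -5.77 and -4.52 in knockout 1 and 2. On the probe used, its signal was at least 920-fold lower in the knockout (log2 difference -10.56, SE 0.49, limma's adjusted p = 0.00236). Cyp3a25 was at least 145-fold lower (adjusted p = 0.00184), Cyp3a59 at least 126-fold lower (adjusted p = 0.00168) and Cyp3a16 at least 113-fold lower (adjusted p = 0.00277). Cyp3a57 was at least 43.4-fold lower (adjusted p = 0.00248) and Cyp3a41b at least 27.2-fold lower (adjusted p = 0.026). These folds are lower bounds: the wild-type mean was set against the mean, per knockout array, of the higher of the probe's own signal and the lowest signal among probes well above background. A second Cyp3a11 probe had levels of 2.42 and 2.86 in wild type and was still well above background in knockout 1 (-3.48) but not in knockout 2. Its measured signal was 92.8-fold lower, so the bound of 920-fold holds for the probe used and not for the gene. Cyp3a44 and a second Cyp3a59 probe were not well above background on any array. As a list the cluster had a median log2 difference of -8.74, or -6.90 with its genes at their bounds, and all 6 genes passed over all genes and adjusted over the list alone. Camera with its preset correlation gave an adjusted p of 4.39e-76, with an adjusted p = 0.202 with an estimated correlation. Genes of this family are close in sequence, so signal on 1 member's probe may include transcripts of another. Within the slide that held both genotypes, the Cyp3a11 difference was -11.55. Without wild type 1 or wild type 2, none of the 6 calls passed the threshold (Cyp3a11 adjusted p = 0.0754 and 0.0855), with a log2 difference of -10.92 and -10.20. Both Cyp3a11 values without a knockout array passed.

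**Figure D1:**
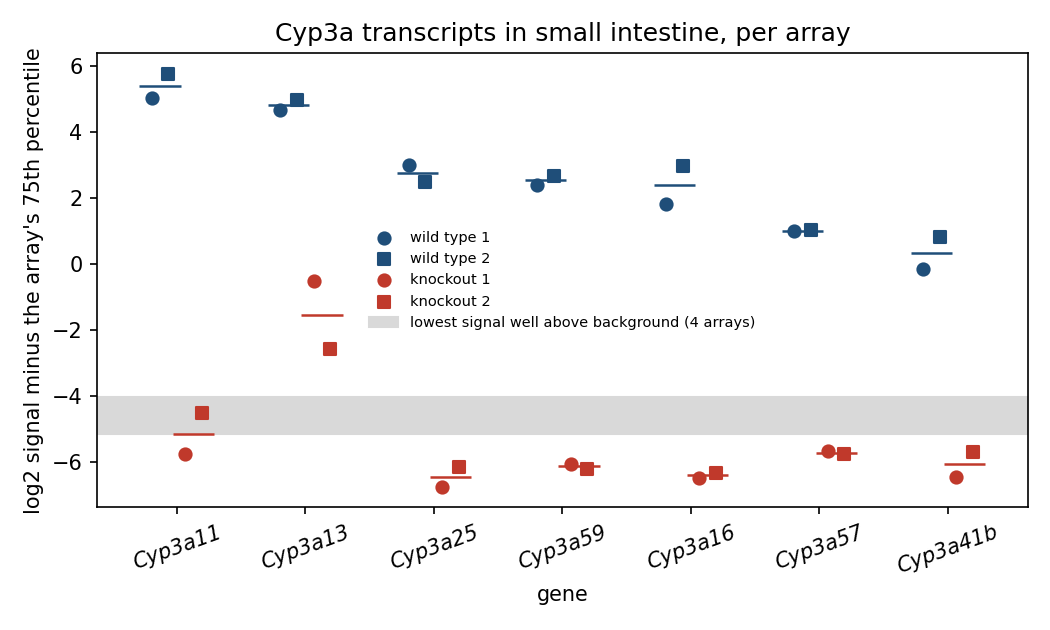
Log2 signal relative to the array's 75th percentile (vertical axis) of the 7 tested Cyp3a genes (horizontal axis), with 1 point per array, short lines at the mean of each genotype, and a grey band over the lowest signals well above background on the 4 arrays. Knockout points of the 6 cluster genes lie in or under the band, and those of Cyp3a13 lie above it at -0.53 and -2.57.

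Cyp3a13 lies apart from the cluster, with 121 protein-coding genes between them in the reference annotation. Its level was 4.83 ± 0.22 in wild type and -1.55 ± 1.44 in knockout, an 83.0-fold difference (log2 difference -6.37, SE 0.64). It was well above background on all 4 arrays and did not pass the threshold over all genes (limma's adjusted p = 0.105), nor without wild type 1 (0.831) or wild type 2 (0.858). It passed without knockout 1 (adjusted p = 1.8e-09) and without knockout 2 (adjusted p = 3.61e-07), where the knockout arrays' own spread no longer enters the fit. A second probe for Cyp3a13 was 38.4-fold lower. Whether Cyp3a13 is itself altered in this line is not given in the sources used here, and binding of other Cyp3a transcripts to its probes was not checked. Within the shared slide the difference was -5.51. Of the genes that flank the cluster, 25 fixed beforehand were tested and 0 passed, also when adjusted over the list alone. Their median difference was 0.10, or 0.18 within the shared slide, and the preset list test gave an adjusted p of 0.203. Zfp655, the gene with the smallest p among them, had a log2 difference of 0.47 (SE 0.26). The flanking gene 1700001J03Rik was not among these 25 and is given under Other observations.

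Outside the Cyp3a genes no transcript passed the threshold. Limma called 0 genes higher and 6 lower, and the 6 were the cluster genes above. At an unadjusted p under 0.05 there were 24 higher and 39 lower, 63 in all, where 720 would be drawn by chance from 14395 genes. Both knockout arrays lay above both wild-type arrays for 8.66% of genes and below them for 6.09%, where chance gives 16.7% in each direction. The knockout arrays correlated less with each other (0.948) than either did with a wild-type array. In simulations the fit recovered 0.2% or 5.2% of 2-fold changes, by the variances used. Counts under chance are therefore no evidence that genotype had no effect. The genes named next differed at least 2-fold in mean measured signal without overlap between genotypes, some of them from signals under background, but none passed the threshold (adjusted p = 1.00 each). On the lower side, Rec8, which encodes a meiotic cohesin subunit, had 4.12-fold lower signal (log2 difference -2.04, SE 0.36). Bhmt, betaine-homocysteine methyltransferase, had 8.65-fold lower signal (SE 0.60), with log2 differences of -2.36 without wild type 1 and -3.86 without wild type 2. Mug1, a gene for a plasma protease inhibitor, was well above background on only 3 of the 4 arrays and had 4.63-fold lower measured signal. Its log2 difference was -1.52 without knockout 1 and -2.90 without knockout 2. Its relative Mug2 and the plasma protein gene Orm3 were not well above background on either knockout array, and were at least 3.59-fold and at least 1.68-fold lower. On the higher side, Ces2a, an intestinal carboxylesterase, was 3.43-fold higher (log2 difference 1.78, SE 0.49), by 2.39 in knockout 1 and 1.17 in knockout 2. Bcl2l15, a gene of the Bcl-2 family, was 2.90-fold higher (SE 0.33), and B3galt5, a galactosyltransferase, 3.40-fold higher (SE 0.64), with log2 differences of 0.81 without knockout 1 and 2.73 without knockout 2. The glutathione transferase gene Gstm4 was 2.40-fold higher (0.59 and 1.93 in the same order) and the transcription factor gene Cebpd 2.04-fold higher (0.65 and 1.40). Fam205c was not well above background in wild type and was at least 1.95-fold higher in knockout on the probe used. With no background filter another probe of the gene was used, with a log2 difference of 0.73, which is under that bound. The other 6 higher genes, Agr3, Xlr3b, Wfdc10, Dppa5a, Pik3cg and Prss12, had log2 differences from 1.17 to 1.30. After normexp, whose offset raises dim signals, the differences of the genes named here were smaller, such as -0.76 for Bhmt, -0.41 for Mug1, 0.23 for Agr3 and 0.15 for Prss12. Without knockout 2 the counts were 135 higher and 298 lower, and without knockout 1 they were 2 higher and 10 lower, where the spread came from the wild-type arrays alone. Of the genes named here, Rec8, Bhmt, Mug1, Mug2, Bcl2l15, Ces2a, Dppa5a, Cebpd, B3galt5 and Gstm4 passed without knockout 2, and Rec8 without knockout 1. Without wild type 1 or wild type 2 the counts were 0 and 0.

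Of 52 gene lists tested with camera and its preset correlation, 16 were higher in knockout and 8 lower past the threshold. With an estimated correlation 0 lists passed: the Cyp3a cluster had the lowest adjusted p, 0.202, and the other lists lay at 0.769 or above. This setting missed even the deleted cluster, so a list that fails it is not thereby shown to be unchanged. Many lists share the value 0.769 through the adjustment. Camera's unadjusted p in this setting was 0.0748 for B and plasma cells and 0.562 for interferon-stimulated genes, both adjusted to 0.769. Fry called 0 lists higher and 1 lower, the Cyp3a cluster. Adjusted over the list alone, single genes passed in 2 lists, those of the Cyp3a cluster and of Cyp3a13. The Cyp3a13 list holds 1 gene, so its p-value was in effect unadjusted. Knockout 1 stood apart: its correlation across genes was 0.966 and 0.962 with wild type 1 and 2 and 0.948 with knockout 2, while the wild-type arrays correlated at 0.979. Of the 16 higher lists, 12 had a median above both wild-type arrays in knockout 1 and not in knockout 2. Without knockout 1, the 2 lists that kept the call were cell cycle and heat shock, and 7 were called lower instead: Cyp2c genes, UDP-glucuronosyltransferases, PPARα targets, fat absorption, interferon-stimulated genes, brush border and distal small intestine. Without wild type 2, 8 of the 16 kept the call, and without wild type 1, 13 did. For no list past the threshold did the median and the direction of the test differ. Among the rest, genes of fatty acid synthesis had a median of 0.05 with a mean of -0.08 and goblet cell genes a median of 0.30 with a mean of -0.06.

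Several drug-metabolism lists were among the higher ones. Some genes belong to several of the lists tested, so calls of related lists are not independent. Targets of PXR and CAR, nuclear receptors that sense foreign compounds, had positive differences in all 19 tested genes, and in 5 of them the genotypes did not overlap (chance gives 16.7% per direction). Their median relative to wild type was 1.29 in knockout 1 and 0.02 in knockout 2 (camera adjusted p = 4.99e-10, and adjusted p = 0.769 with an estimated correlation). Within the shared slide the median difference was 1.36, and without knockout 1 it was 0.02, with the test's direction turned. Gstm2 had differences of 0.66 and 0.72 in knockout 1 and 2, Gstm1 1.99 and 0.42, and the drug efflux pump gene Abcb1a 2.08 and 0.28. Targets of NRF2, the regulator of the oxidative stress response, were positive in 23 of 25 genes, with medians of 0.77 and 0.03 and 0.77 within the shared slide (adjusted p = 9.57e-08, and adjusted p = 0.769 with an estimated correlation). Glutathione transferases were positive in 20 of 22 genes, with medians of 0.59 and 0.08 and 0.71 within the shared slide (adjusted p = 1.24e-06, and adjusted p = 0.769 with an estimated correlation), and Gsta4 had differences of 0.94 and 0.68. Without knockout 1 the NRF2 and glutathione transferase medians were 0.03 and 0.08, with the test's direction turned for NRF2 targets. Cyp2c genes had medians of 1.78 and -0.39, with Cyp2c55 at 3.92 and 0.29. UDP-glucuronosyltransferases were positive in 10 of 11 genes, with a median of -0.37 in knockout 2, while carboxylesterases had medians of 0.72 and -0.17 and AhR targets 0.76 and 0.01. The Cyp2c, UDP-glucuronosyltransferase, carboxylesterase and AhR target medians within the shared slide were 1.59, 1.35, 0.93 and 0.86. These 4 lists passed the preset test with an adjusted p from 0.00575 to 0.0374, and each had an adjusted p of 0.769 with an estimated correlation. Without knockout 1 the test's direction turned for each of these 4 lists. Brush border genes of absorptive enterocytes had medians of 1.08 and -0.38 in the same arrays, and smooth muscle genes -0.84 and 0.54.

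The cell cycle list was higher, with a median above both wild-type arrays in each knockout array, by little for knockout 1. All 29 tested genes had positive differences, and in 18 of them the genotypes did not overlap, where chance gives 16.7%. The list's median relative to wild type was 0.32 and 0.47 in knockout 1 and 2, against 0.28 and -0.28 in the wild-type arrays (camera adjusted p = 6.02e-13, and adjusted p = 0.769 with an estimated correlation). The median difference within the shared slide was 0.49. The preset call held without each array in turn. The median difference was 0.64 and 0.21 without wild type 1 and 2, and 0.47 and 0.32 without knockout 1 and 2. Each of these fits assumed a correlation of 0.01, where the estimated one was 0.36, so they do not test that assumption. Examples are Ube2c, a ubiquitin-conjugating enzyme of mitotic exit (log2 difference 0.68, SE 0.38), the mitotic cyclin gene Ccnb1 (0.58, SE 0.34) and the mitotic kinase gene Aurka (0.55, SE 0.32). Heat shock genes were positive in 14 of 15, and 9 did not overlap. Their medians were 0.26 and 0.43 (adjusted p = 2.11e-06, and adjusted p = 0.769 with an estimated correlation), with the co-chaperone gene Dnajb1 at 0.79 and 0.66 and Hsph1 at 0.38 and 1.01. Within the shared slide the median difference was 0.21, and without knockout 2 the heat shock list had an adjusted p of 0.239. No single gene of either list passed, also when adjusted over the list alone.

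**Figure D2:**
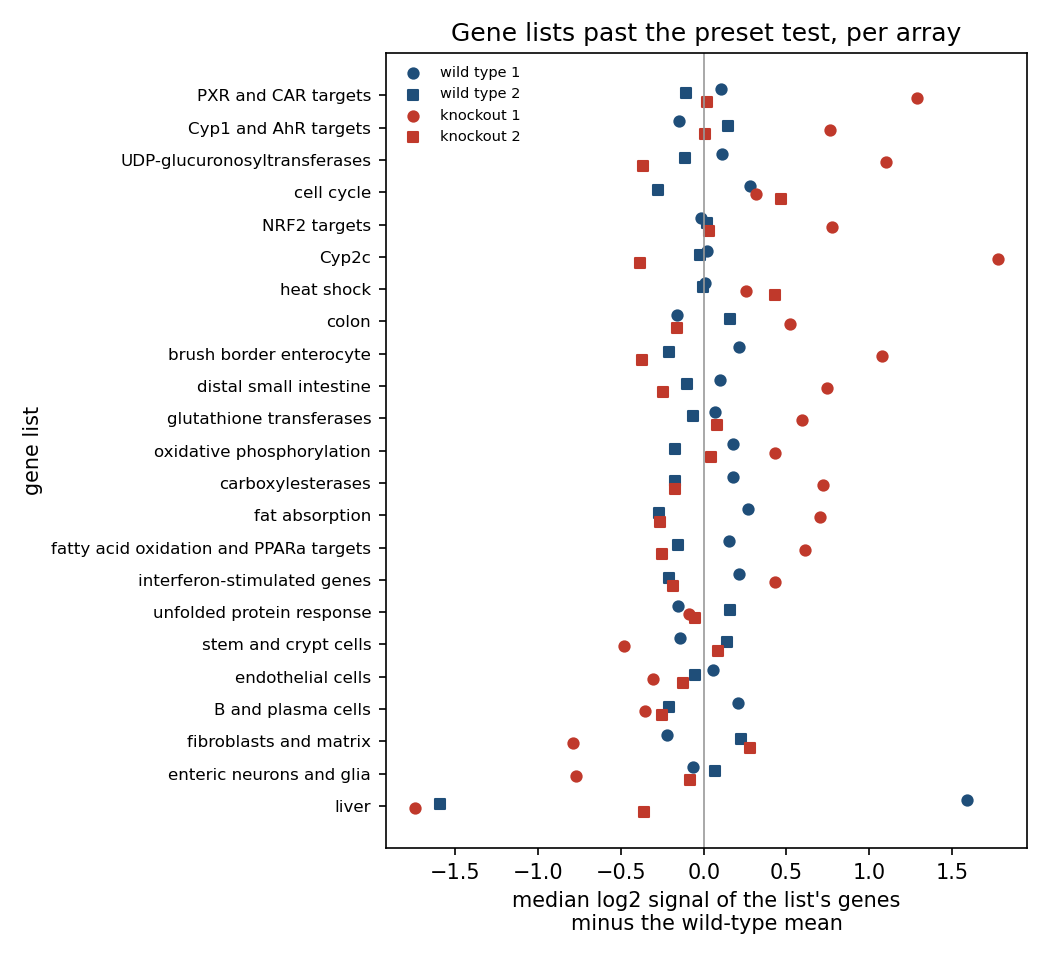
Median log2 signal of each list's genes minus the wild-type mean (horizontal axis) for the lists past the preset test, without the Cyp3a cluster (vertical axis), with 1 point per array and the wild-type points mirroring each other about 0 by construction. Knockout 1 lies far from the other arrays in many lists, such as 1.29 against 0.02 in knockout 2 for targets of PXR and CAR, and both knockout arrays lie at 0.26 or above in the heat shock and cell cycle lists.

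Most lists of absorptive functions and of fat uptake and oxidation were higher in knockout 1 and not in knockout 2. All 30 tested brush border genes had positive differences and in 0 of them were the genotypes apart (camera adjusted p = 0.00081, and adjusted p = 0.769 with an estimated correlation). The brush border median within the shared slide was 1.30. Sis, the sucrase-isomaltase gene, had differences of 1.51 and -0.03 in knockout 1 and 2. Fat absorption genes had medians of 0.70 and -0.26, fatty acid oxidation and PPARα targets 0.61 and -0.25, distal small intestine genes 0.75 and -0.25, colon genes 0.52 and -0.16, oxidative phosphorylation genes 0.43 and 0.05, and interferon-stimulated genes 0.43 and -0.19. In that order, their medians within the shared slide were 0.98, 0.77, 1.04, 0.51, 0.62 and 0.68. These 6 lists passed the preset test, with adjusted p from 0.000101 to 0.0395, and each had an adjusted p of 0.769 with an estimated correlation. Without wild type 2 their median differences, in the same order, were 0.01, 0.02, 0.14, 0.27, 0.04 and -0.09. Without wild type 1 they were 0.48, 0.33, 0.45, -0.05, 0.42 and 0.33. Apob, which encodes the main protein of chylomicrons, had differences of 0.92 and 0.14. Genes of cholesterol synthesis, with medians of 0.04 and 0.17, did not pass (median difference 0.12, adjusted p = 0.183), nor did those of fatty acid synthesis, with medians of -0.19 and 0.19 (adjusted p = 0.725), nor those of bile acid handling (0.11, adjusted p = 0.71).

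The lists that were lower held genes of other cell types, the liver and the unfolded protein response. Genes of enteric neurons and glia had medians of -0.77 and -0.08 (camera adjusted p = 7.81e-06), with Gap43, a growth cone protein, at -0.84 and -0.41 and the neuropeptide gene Vip at -0.52 and -0.24. B and plasma cell genes were negative in all 10, with medians of -0.36 and -0.25 against 0.21 and -0.21 in wild type (adjusted p = 0.000475). Endothelial genes had medians of -0.31 and -0.13 (adjusted p = 0.00312), fibroblast and matrix genes -0.79 and 0.28 (adjusted p = 0.00333), stem and crypt genes -0.48 and 0.09 (adjusted p = 0.0425), and genes of the unfolded protein response -0.09 and -0.05 (adjusted p = 0.0339). Each of these 6 lists had an adjusted p of 0.769 with an estimated correlation. In the order given, their medians within the shared slide were -0.76, -0.04, -0.26, -0.97, -0.51 and -0.24. Without knockout 1 the call was lost for neurons and glia (adjusted p = 0.357), endothelial (0.237), stem and crypt (0.75) and unfolded protein response genes (0.0739), and fibroblast genes were called higher (0.00628). Without wild type 1 it was lost for B and plasma cell (0.205) and endothelial genes (0.068), and without knockout 2 for B and plasma cell (0.173), endothelial (0.092) and unfolded protein response genes (0.435). Without wild type 2 it was lost for stem and crypt (0.544), fibroblast (0.932) and unfolded protein response genes (0.862), the last 2 with the test's direction turned. Liver genes had medians of 1.59 and -1.59 in wild type 1 and 2 and -1.74 and -0.36 in knockout 1 and 2 (adjusted p = 4.48e-06, and adjusted p = 0.769 with an estimated correlation), and without knockout 1 the adjusted p was 0.0567. Without wild type 1 the direction turned (median 0.13, adjusted p = 0.193), so the lower call rested on wild type 1. Within the shared slide the liver median was -0.12. The 28 lists that did not pass the preset test had an adjusted p of 0.0564 or above, among them goblet, Paneth, tuft and enteroendocrine cells, T and NK cells, smooth muscle, pancreas and red blood cells. Transcripts of the Y-linked genes Ddx3y and Eif2s3y differed by 0.22 (SE 0.27) and 0.04 (SE 0.30), and no Xist probe was well above background on any array.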

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

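Testing every probe on its own, the difference within the shared slide and normexp on median signals were chosen after seeing the data. Normexp on mean signals was not run. Slide as a random block could not be fitted, and camera has no robust setting. The count of 6 lower genes stayed between 5 and 7 under the other scalings, the authors' table, no background filter, mean probes and both variance settings, and 0 genes were higher in these. Of the 5 after normexp, 4 were among the 6. Higher lists numbered 12 to 16 and lower lists 6 to 9 in these and with the stricter filter. The authors' table repeats the main values within 0.01 apart from row centring, so it is no independent check. Requiring all 4 arrays above background left 0 lower genes, since it removes the cluster genes by construction. Testing 24006 probes singly called 7, all of Cyp3a genes. Leaving out arrays gave 0 to 135 higher genes, 0 to 298 lower genes, 7 to 25 higher lists and 7 to 18 lower lists. Without a knockout array the spread came from the wild-type arrays alone. That drops the wider gap of the knockout pair, with 2811 genes over 2-fold apart against 773 for the wild-type pair. Other causes were not tested. Camera with an estimated correlation called 0 lists, and fry 0 higher and 1 lower, the Cyp3a cluster (adjusted p = 0.0354). Cyp3a11 was -8.55 as the mean of its probes, ranged from -11.19 to -9.93 with an array left out, was -11.55 within the shared slide, and was -6.23 after normexp, whose offset of 50 raises dim signals by construction. After normexp Cyp3a16 and Cyp3a41b no longer passed (adjusted p = 0.271 and 1.00), and Cyp3a13 passed (adjusted p = 0.0207), as it did with no background filter (adjusted p = 3.66e-05). For the 23 other named genes, 336 alternative values held 12 lost and 22 gained calls. Within the slide 7 untested values moved by more than the replicate spread. Directions turned in 0, which no overlap between genotypes forces there and with an array left out. Normexp kept directions but shrank dim genes, such as Mug2 from -2.97 to -0.24 and Fam205c from 3.22 to 0.19. Of the list members named by the rule, 56 of 192 turned direction without knockout 1, 16 without wild type 2, 6 without wild type 1 and 6 without knockout 2. The median of 3 lists (sulfotransferases, retinoid metabolism and Paneth cells) changed sign under another scaling. Normexp shrank the medians of most called lists, though not of stem and crypt cells (-0.17), among them the Cyp3a cluster (-3.50), liver (-0.44), neurons and glia (-0.11), B and plasma cells (-0.10), heat shock (0.10) and cell cycle (0.21). Dim signals limit the cluster genes to lower bounds.

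Replicate numbers are shared between genotypes, and the labels speak of 2 experiments without saying whether same-numbered samples belong to 1 of them. The deviations of same-numbered arrays correlated at 0.05 across genes. With the replicate block 6 genes were higher and 26 lower, with 21 higher and 6 lower lists. The block added calls of Cyp3a13 (adjusted p = 1.84e-35), Rec8, Bhmt, Mug1, Mug2, Bcl2l15, B3galt5, Cyp2c55, Gkn2, Prrx2 and others. Gkn2 passed as lower though higher in knockout 2 than wild type 2, so a p-value here need not reflect a gene's own spread. Parting the arrays by genotype gave 63 genes at an unadjusted p under 0.05, by replicate number 1253 and by the shared slide 1263, with 6, 8 and 0 past the threshold. Those larger counts point to a structure of the samples other than genotype, and 3 splits are too few for a share under 0.05.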

Other observations

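All tests of explanations below were chosen after the results were seen. Genes of the circadian clock did not pass as a list (camera adjusted p = 0.131). Among them Nr1d1, a repressor in the clock, had log2 differences of -0.60 and -0.91 in knockout 1 and 2, Cry2 -0.77 and -0.39, and Per1 0.27 and 1.30. Chac1, a stress-induced gene of glutathione breakdown, was not well above background in either knockout array and was at least 2.12-fold lower. None of these passed the threshold.

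A gene beside the cluster, 1700001J03Rik, was not among the flanking genes fixed beforehand and was chosen after its values were seen. It is the third protein-coding gene past the cluster in the reference annotation, and its signal was -3.35 ± 0.59 (SD, n = 2) in wild type and -6.34 ± 0.46 in knockout, not well above background in knockout, which gives at least 2.12-fold lower signal without passing the threshold (limma's adjusted p = 1.00). Its next neighbours Rnf6 and Cdk8 differed by 0.06 (SE 0.29) and 0.15 (SE 0.27). Prrx2, also chosen after its values were seen, rested on 1 spot of knockout 2 with a signal of 93527, where the highest value on the other arrays was 26.6. Of the 26 spots around it, 6 carried a flag for uneven background, where knockout 2 had 14 such flags in all. The highest background anywhere on knockout 2 was 37800, against 31 to 38 on the other arrays.

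Genes of gastric surface mucous cells, chosen after their values were seen, varied between arrays of 1 genotype and had higher list medians in both arrays numbered 2, which may or may not share an experiment, while other stomach genes did not all do so. Gkn2 had levels of 1.27 and 6.49 in wild type 1 and 2 and -6.64 and 7.24 in knockout 1 and 2, and a list of 13 surface mucous genes, all tested and 1 also in a list fixed beforehand, had medians of -1.06, 1.87, -2.62 and 2.06 in that order, against 0.29, -0.08, -0.97 and 0.65 for 3 gland genes, 0.10, 0.71, -1.05 and 0.29 for 5 parietal and chief cell genes and -0.20, -0.30, 0.31 and -0.03 for 5 squamous genes. For acid-secreting stomach, the parietal pump genes Atp4a and Atp4b reached at most -5.63 in wild type 2 and knockout 2, with 0 values well above background. Their probes were not well above background on any array, so whether they would detect a small amount of such tissue is unknown. Cblif, the gastric intrinsic factor gene, was well above background in those arrays alone (-3.01 and -2.86). These values do not decide whether acid-secreting stomach was a source. Array brightness is argued against, since wild type 2 was 2.03 times as bright as knockout 2 and the remaining arrays lay between them. Surface mucous cells of the stomach outlet carried along at dissection may be a source, which was not tested, and no explanation by genotype was tested, since each genotype has arrays of both kinds.

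Targets of PXR and CAR were raised mainly in knockout 1. The slide is argued against, since knockout 1 exceeded wild type 2 on the same slide by a median of 1.36 (95% bootstrap interval 0.84 to 1.88 over genes). A larger share of absorptive epithelium is a candidate explanation: relative to the brush border list of the same array the targets lay 0.21 higher in knockout 1 (interval -0.38 to 0.69) and 0.39 higher in knockout 2 (interval -0.02 to 0.72). Both intervals hold 0, which is not a sign of equality. All intervals in this paragraph resample genes as if they were independent, so they are too narrow and hold no variation between samples. The estimated correlation was 0.68 among targets of PXR and CAR and 0.82 among brush border genes. In wild type 1 and 2 the targets lay at -0.11 and 0.11 relative to the brush border list, mirrored by construction and under both knockout values. An effect of the genotype stays open, and 2 arrays per genotype do not part it from the makeup of the samples.

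Outside Cyp3a, 76 genes were at least 2-fold lower in mean measured signal without overlap between genotypes, Bhmt, Mug1, Mug2 and Orm3 among them, but 27 of the 76 were not well above background on either knockout array and only 5 of these have a bound of at least 2-fold. Stretches of chromosome from another strain would place such genes near each other: outside gene families 2 pairs lay within 5 tested genes, where random sets of like expression had a median of 2 (permutation p = 0.576 over 10000 sets), and with families 4 pairs (permutation p = 0.159), which shows no excess but excludes nothing, since the count needed to detect a stretch is unknown. Liver tissue in the wild-type samples is a candidate explanation for Bhmt and the plasma protein genes, and the liver list was higher in wild type 1 than in knockout 1 and 2, by medians of 4.65 (interval 1.27 to 5.69) and 2.20 (interval 0.83 to 3.03). Wild type 2 differed from knockout 1 by a median of 0.12 (interval -0.18 to 1.48) and from knockout 2 by -0.65 (interval -2.59 to -0.02), so 2 of the 4 pairs go with liver, 1 goes the other way by a narrow margin and 1 does not decide. Bhmt, Mug1, Mug2 and Orm3 were all higher in wild type 2 than in knockout 2 (Bhmt -1.60 against -3.53), against the list. Their choice for no overlap between genotypes requires this, so it decides nothing. The liver intervals also resample genes as if independent and are too narrow. All of these explanations and an effect of the genotype stay open.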
